A study of Mus musculus with 7 samples.

How the data were processed

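RNA-seq was measured in 7 samples of CD8 T cells sorted from MCA205 tumours 14 days after implantation, at least 30000 cells per condition, with libraries made after poly(A) selection from 75 ng of RNA, per the labels' protocols. The groups were 4 ENT1KO and 3 WT samples, taken from the sample titles, with replicate numbers as the titles give them.

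The authors deposited 2 tables. The first holds TPM for 55357 genes, and each deposited TPM column sums to the same total, so it keeps no depth. The second is a comparison of knockout and WT. Its sample columns hold a signal, the gene read counts that the authors divided by 1 size factor per sample, and its mean column is the mean of these. The table also holds log2 fold changes with standard errors and log2 group means, deposited by the authors, the authors' test statistic as a score, and p-values with adjusted p-values deposited as the authors computed them. The submitters' processing notes name Trimmomatic 0.35 and 0.38, STAR 2.7.1a, RSEM, DESeq2 1.30.1, DESeq and the build GRCm39, without roles, and the deposited comparison is named for DESeq, per the file headers and names. The annotation release and the read filters are not given in the sources used here. The TPM table is described as stranded, per the file headers and names. Coordinates are those of the deposited table, and the reference annotation at hand was of another build and was not used for positions.

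Every value of a normalized count column was a whole multiple of the smallest value in that column (100% within a tolerance of 0.01), which gives totals of 18624318, 19635168, 19120692 and 18993105 reads for ENT1KO replicates 11, 12, 14 and 15 and 18632462, 19660792 and 18790100 for WT replicates 1, 2 and 3. For WT replicates 1 and 3 the step lies so near 1 that the unit check did not accept it as proof of whole reads. A count test was therefore not run on any column, and the planned branch for TPM was used, with the authors' DESeq2 results, as deposited, beside it. No count intervals were computed.

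Genes with at least 1 TPM in at least 3 samples were tested (13798 genes). The test was limma-trend with robust empirical Bayes on log2(TPM + 1), with genotype as the only term and Benjamini-Hochberg adjustment (limma 3.58.1, R 4.3.3). A fold change on this scale understates the change of low genes. Single values were compared with exact two-sided permutation tests over the 35 splits of the 7 samples, which cannot give less than 0.0286. Of 41 gene lists, 684 of 695 genes matched a symbol in the table. Lists with at least 3 tested members (39) were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39, and with camera at an estimated correlation and fry beside it. Fry tests whether a list's genes move one way and does not compare them with other genes. The sex-linked check list was described and not tested. List levels per library are the summed TPM of members. Principal components used the 1000 most variable tested genes, and genes within 10 Mb of Slc29a1 were compared with the rest by Fisher's exact test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

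Genes are named by a rule. It takes Slc29a1, the 12 rises and the 12 falls with the largest log2 difference among called genes whose groups do not overlap and whose mean is at least 5 TPM, the 2 members with the smallest p of each pathway list, and the 2 most abundant members of each other-cell-type list. Receptor and immunoglobulin segments, unnamed models, pseudogenes and sex-linked check genes were left out of the rises and falls. Some genes are not reported here, although the counts include them. Other list members are named as examples of their list and were chosen after their values were seen. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined. The fibroblast and tumour list covariate, the scaling to the CD8 T cell identity list and the test on log2(normalized count + 1) were added after the data were seen. The scaling subtracts the mean log2 level of the identity list in each library from each gene. All genes then share that list's spread between libraries, which limma treats as separate information from each gene. Limma adjusted p on this scale are therefore too small. For Slc29a1 the adjusted p was 1.85e-14 there and 0.00121 on TPM, although its standard error was larger there (0.33 against 0.13). The alternatives were quantile normalization, filters of a value above 0 in 1 sample and of 5 TPM in 3 samples, array weights, pseudocounts of 0.1 and 5, the macrophage list level as a covariate, protein-coding genes only, and leaving out each library.

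The scripts were tested on simulated data made from the means and spread of the 13798 genes, 4 samples against 3. For this comparison limma-trend recovered 25.4% of genes changed 1.5-fold, 59.7% of those changed 2-fold and 87.9% of those changed 4-fold, and 3 of 118 calls were false. The raised list was called and 0 other lists were. The simulated genes varied independently of each other and most were left unchanged, unlike in the data. In the data the estimated correlation reached 0.93, for the CD8 T cell identity list. The simulation therefore does not test camera on lists whose genes vary together.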

Results

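The data were poly(A)-selected RNA-seq libraries of CD8 T cells that had been sorted, as live CD45-positive CD8-positive cells, from subcutaneous MCA205 tumours 14 days after implantation. MCA205 is a transplantable mouse fibrosarcoma line of the C57BL/6 background. 4 samples came from recipients lacking ENT1 (ENT1KO, replicates 11, 12, 14 and 15) and 3 from wild-type recipients (WT, replicates 1, 2 and 3). ENT1, encoded by Slc29a1, is an equilibrative transporter that carries adenosine and other nucleosides across the plasma membrane. The comparison addresses whether loss of this transporter in the host changes the transcriptome of tumour-infiltrating CD8 T cells, with nucleotide metabolism and adenosine signalling in view. Each library held 18624318 to 19660792 gene-assigned reads, as read from the steps of the normalized counts, so depth was close to equal between genotypes. The labels do not say that each sample is a separate animal, so the p-values measure the spread between these samples. Values are means ± SD in TPM, a length-corrected abundance scaled to the same total in each library, over n = 4 ENT1KO and n = 3 WT libraries unless stated otherwise, and log2 differences are ENT1KO minus WT on the log2(TPM + 1) scale, which understates the change of low genes.

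Slc29a1, the targeted gene (chromosome 17, 45896126 to 45910532, GRCm39), was lower in each ENT1KO library than in any WT library. It stood at 13.6, 13.2, 17.6 and 15 TPM in ENT1KO replicates 11, 12, 14 and 15, and at 51.0, 58.9 and 49.7 TPM in WT replicates 1, 2 and 3. The means were 14.8 ± 2.001 (SD, n = 4) and 53.2 ± 4.94 TPM (SD, n = 3), a log2 difference of -1.78 with a standard error of 0.13 (limma-trend adjusted p = 0.00121). The exact two-sided permutation test over the 35 splits of the 7 samples gave p = 0.0286, the smallest that these group sizes allow. In the authors' deposited table the log2 fold change was -1.87 with an adjusted p of 7.65e-28. Transcript from the locus was still present in the ENT1KO libraries, at 15 TPM in replicate 15 and 17.6 TPM in replicate 14, whose summed fibroblast and tumour lists were 7.33 and 846 TPM, and which part of the gene was deleted is not given in the sources used here. In WT replicates 1, 2 and 3 the summed fibroblast and tumour list was 5734, 7426 and 3864 TPM. How much of the WT Slc29a1 level came from cells other than T cells was not tested. With the macrophage list level as a covariate the difference was -1.56 (limma adjusted p = 0.403), and with the fibroblast and tumour list level it was -1.49 (limma adjusted p = 0.496).

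The ENT1KO and WT libraries formed separate groups. Over the 1000 most variable tested genes, the first principal component held 88.1% of the variance and placed all 4 ENT1KO libraries on one side of the 3 WT libraries, with ENT1KO replicate 14 nearest to WT. The second component held 3.4%. The distance between the group centroids was larger than in each other split of the samples (exact two-sided permutation p = 0.0286 over 35 splits). Across genes, Pearson's r lay between 0.958 and 0.979 within ENT1KO, between 0.960 and 0.975 within WT, and between 0.784 and 0.948 between genotypes.

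**Figure D1:**
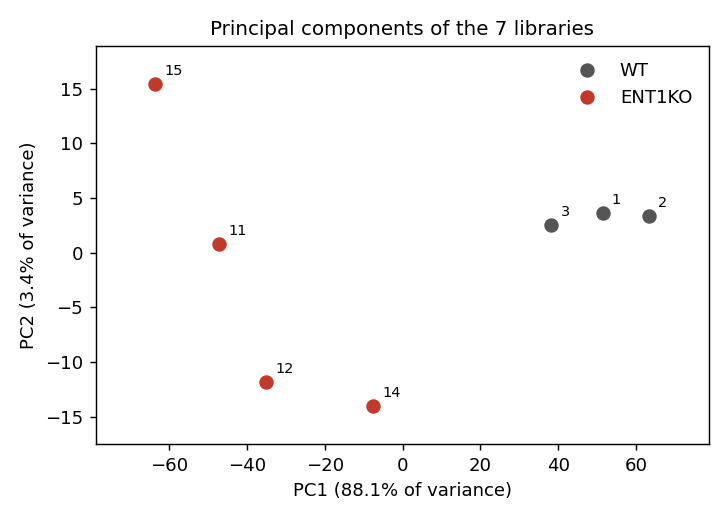
Principal components of log2(TPM + 1) over the 1000 most variable genes, with component 1 on the horizontal axis, component 2 on the vertical axis (both in score units) and 1 point per library, numbered by replicate. The 4 ENT1KO libraries lie left of the 3 WT libraries along the component that holds 88.1% of the variance.

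Of 13798 genes tested, 6982 passed a limma-trend adjusted p of 0.05, 3800 higher and 3182 lower in ENT1KO. Among those, 844 rose and 2029 fell by more than 2-fold, and the largest falls were those of matrix genes described next. The median of all tested genes was 0.145 on the log2(TPM + 1) scale. The values of the groups did not overlap for 55.2% of genes, where chance gives 5.71%. On other scalings the balance of directions moved. The same test on the deposited normalized counts called 2894 higher and 3859 lower, 42.9% higher against 54.4% on TPM, with a median of all genes lower by 0.145 than on TPM. Relative to the mean level of the CD8 T cell identity list, a scaling chosen after the data were seen, 22 genes were higher and 9255 lower, with the median of all genes shifted by -1.18. Limma adjusted p on that scale are too small, since all genes share the spread of the identity list, so these counts are too high. Without WT replicate 2, 4840 genes passed and 2315 of them were higher. With the macrophage list level as a covariate, 4 genes passed in limma (1497 at an unadjusted p under 0.05), and with the fibroblast and tumour list level none did (1241 unadjusted). The summed levels of both lists are free of overlap between the genotypes, so a covariate of this kind takes up much of the genotype difference.

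Genes of tumour and stromal cells were the most strongly lowered in the ENT1KO libraries. All 19 tested genes of the fibroblast and tumour cell list fell, with a median log2 difference of -4.79 (camera adjusted p = 2.83e-08; adjusted p = 0.601 with an estimated correlation). Col3a1, a fibrillar collagen, was at 66.1 ± 104 against 1251 ± 383 TPM, Postn (periostin) at 64.9 ± 96.3 against 1295 ± 457 TPM, and Sparc, a matrix glycoprotein, at 31.6 ± 43.2 against 729 ± 239 TPM. Mgp, Bgn, Col1a2, Col1a1, Acta2 (smooth muscle actin), Serpinh1 (a collagen chaperone), Crabp1, Htra1 and Tm4sf1 completed the 12 largest falls, with log2 differences from -5.84 to -5.15 and limma adjusted p from 0.00233 to 0.0149. The summed level of the fibroblast and tumour list was 275 ± 387 TPM in ENT1KO and 5674 ± 1782 TPM in WT (exact permutation p = 0.0286), and within ENT1KO it ran from 7.33 TPM in replicate 15 to 846 TPM in replicate 14. Without WT replicate 2, the limma adjusted p was 0.0686 for Col3a1, 0.0718 for Postn, 0.0563 for Sparc, 0.082 for Crabp1 and 0.0689 for Tm4sf1. Krt18 and Krt8, keratins of the keratinocyte and epithelial list, also fell (Krt18 2.1 ± 2.29 against 69.4 ± 22.4 TPM), while Sfn of the same list rose (24.9 ± 4.75 against 12.1 ± 5.6 TPM). As a whole that list of 7 tested genes did not pass (camera adjusted p = 0.491), with a positive median of 0.34 but a negative mean of -0.85 and a negative camera direction. Fry called it lower (fry adjusted p = 0.00902).

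Myeloid transcripts were lower in ENT1KO as well. In the macrophage and monocyte list 18 of 20 tested genes fell and 1 rose, with a median of -3.07 (camera adjusted p = 7.07e-06; adjusted p = 0.601 with an estimated correlation). Lyz2 (lysozyme) stood at 172 ± 139 against 1272 ± 305 TPM, and the complement genes C1qa, C1qb and C1qc had log2 differences of -3.35, -3.33 and -3.37. The riser, Ly6c2, is expressed by memory-type CD8 T cells as well as by monocytes. In the dendritic cell list 8 of 14 genes fell and none rose (camera adjusted p = 0.0028; adjusted p = 0.601 with an estimated correlation), among them the class II genes H2-Eb1 (137 ± 73.3 against 478 ± 136 TPM) and H2-Aa (133 ± 72.6 against 460.1 ± 114 TPM). In the neutrophil and mast cell list 9 of 10 fell (camera adjusted p = 5.75e-05; adjusted p = 0.601 with an estimated correlation), with S100a9 at 1.59 ± 1.31 against 36.7 ± 5.199 TPM and Mmp9 at 1.12 ± 1.18 against 31.7 ± 11.4 TPM. Haemoglobin genes led the erythroid and platelet list, 6 of 7 of which fell (camera adjusted p = 0.00268; adjusted p = 0.601 with an estimated correlation); Hbb-bs was at 65.2 ± 44.05 against 524 ± 326 TPM and Hba-a2 at 67.9 ± 46.4 against 518 ± 323 TPM. In the endothelial list 7 of 8 fell (camera adjusted p = 0.00183; adjusted p = 0.601 with an estimated correlation), Eng among them (3.63 ± 1.34 against 15.9 ± 3.85 TPM), and Pecam1, which T cells also express, rose (30.3 ± 7.39 against 18.9 ± 2.12 TPM), a call lost without ENT1KO replicate 15 or WT replicate 1 or 2 (limma adjusted p from 0.0529 to 0.0713) and on normalized counts, at 0.49 (limma adjusted p = 0.0581). The counts over each list alone were the same for the fibroblast, macrophage, dendritic, neutrophil, erythroid, endothelial and keratinocyte lists as those over all genes.

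CD8 T cell genes were higher in ENT1KO. All 14 genes of the CD8 T cell identity list rose, also when adjusted over the list alone, by a median of 1.14 (camera adjusted p = 0.000258; adjusted p = 0.601 with an estimated correlation). Their summed level was 11951 ± 992 TPM in ENT1KO against 5621 ± 2388 TPM in WT, 2.13 times as high (exact permutation p = 0.0286). Trac and Trbc2, the constant regions of the T cell receptor chains, were at 1635 ± 114 against 772 ± 334 TPM and 1516 ± 137 against 687 ± 295 TPM. On normalized counts Trbc2 lost its call, at a log2 difference of 0.78 against 1.23 on TPM (limma adjusted p = 0.055). Of 131 tested T cell receptor and immunoglobulin V segments, 40 rose and none fell in limma-trend, where 51 had an unadjusted p under 0.05. Relative to the identity list, 2 of these segments were higher and 16 lower. The NK cell list had 3 rises and 4 falls among 11 genes (camera adjusted p = 0.783), with a median of 0.46 but a mean of -0.25. Klrk1, the NKG2D receptor that CD8 T cells share, rose (779 ± 216 against 328 ± 113 TPM), whereas Tyrobp and Fcer1g, adaptors that myeloid cells share, fell by 2.15 and 1.55 on the log2 scale. In the B cell and plasma cell list 2 genes rose and 2 fell among 7 (camera adjusted p = 0.907; median 0.20, mean -0.30), with Ighm at 135 ± 34.4 against 74.7 ± 21.96 TPM and Blnk at 1.98 ± 0.8701 against 10.9 ± 2.46 TPM. In the list of CD4 and regulatory T cell markers 3 rose and 2 fell among 10 (camera adjusted p = 0.781). Cd4 and Foxp3 fell by 0.73 and 0.70 on the log2 scale and Ctla4 rose (471 ± 109 against 180.4 ± 55.96 TPM), while Tnfrsf4 did not pass (56.9 ± 21.9 against 34.5 ± 12.1 TPM, limma adjusted p = 0.184). The NK, B cell and CD4 counts were the same when adjusted over the list alone. Ighm lost its call without any one of ENT1KO replicates 11, 14 and 15 or WT replicates 1 and 2 (limma adjusted p from 0.0596 to 0.114), and Tnfrsf4 passed without ENT1KO replicate 15 (0.0243). Trdc, the one tested gene of the gamma-delta T cell list, had a log2 difference of 0.54, below the size needed for a list test.

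**Figure D2:**
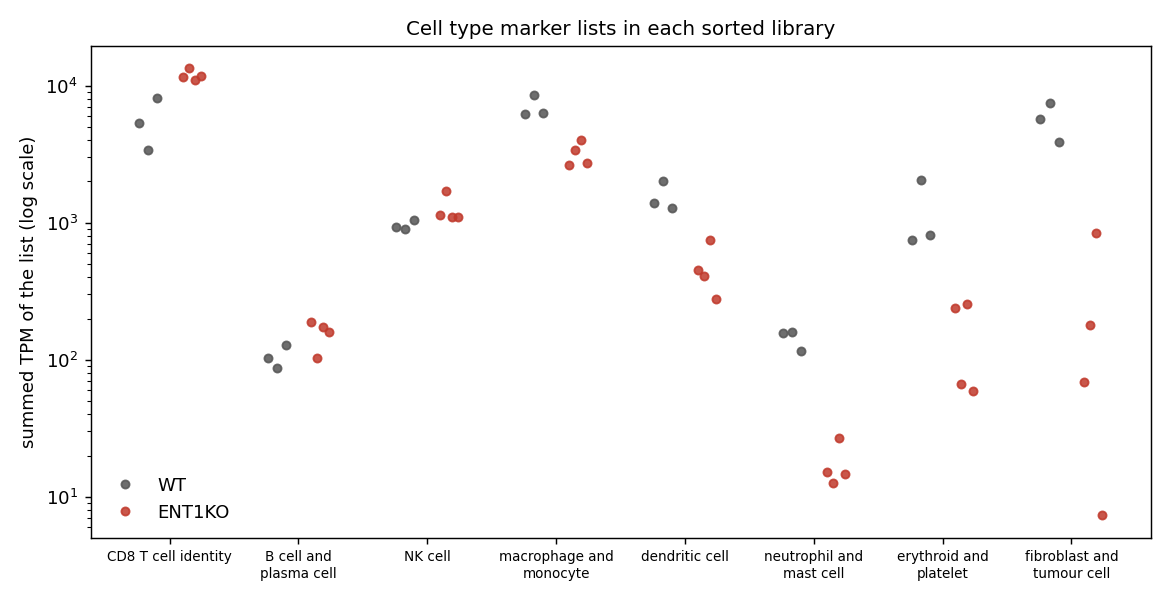
Summed TPM of 8 marker lists (horizontal axis) in each library, on a log scale, with WT libraries in grey and ENT1KO libraries in red. The CD8 T cell identity list averages 11951 TPM in ENT1KO and 5621 TPM in WT, and the fibroblast and tumour list 275 and 5674 TPM.

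Ifi208 had the largest of the 12 named rises in ENT1KO. This gene, a member of the p200 family on chromosome 1 (173501241 to 173525961), rose from 8.85 ± 4.89 to 93.9 ± 12.8 TPM (log2 3.38, SE 0.30, limma adjusted p = 0.00121). Its neighbours Ifi213 (142 ± 39.8 against 32.7 ± 8.77 TPM) and Ifi214 (50.9 ± 6.902 against 12.8 ± 5.83 TPM) rose by 2.09 and 1.99, and Gbp10, a guanylate-binding protein on chromosome 5, rose by 2.11 (36.5 ± 10.3 against 7.55 ± 1.56 TPM). Ly6c2 was the most abundant of the 12 (1874 ± 298 against 530.2 ± 310.4 TPM). Rapgef4, a cAMP-activated exchange factor, was at 13.2 ± 7.03 against 2.43 ± 1.12 TPM, Hid1 at 47.97 ± 14.3 against 12.3 ± 5.602 TPM, Art2b, an ADP-ribosyltransferase of T cells, at 9.19 ± 2.99 against 1.76 ± 1.01 TPM, and Eps8l1 at 28.2 ± 8.87 against 6.91 ± 1.94 TPM. The list was completed by the small RNA genes Mir24-2 (9.41 ± 3.26 against 0.873 ± 1.51 TPM) and SNORA21B (11.8 ± 6.39 against 1.66 ± 2.88 TPM) and by Erdr1 (145 ± 30.9 against 35.6 ± 15.7 TPM). Erdr1 lies at the X and Y chromosome ends, where reads can be shared between copies, and on the log2(normalized count + 1) scale its difference was -0.94, the opposite sign, with an authors' log2 fold change of -1.15 (adjusted p = 0.165 in the authors' deposited table). Mir24-2 and SNORA21B, short genes whose own transcripts poly(A) selection captures poorly, had adjusted p of 0.179 and 0.0608 in the authors' deposited table, and SNORA21B had a limma adjusted p of 0.0715 without WT replicate 2. Which transcripts gave the reads of these 2 small RNA genes was not tested. The p200 and Gbp genes belong to paralogous families that can share reads. These genes are named for their large rises, which favours values above the CD8 T cell identity list. After subtraction of that list, Ifi208 was 2.20 higher, Ifi213 0.90, Ifi214 0.81, Gbp10 0.93 and Ly6c2 0.77. Of the 12, Rapgef4, Art2b and Eps8l1 did not pass there, at 0.79, 0.70 and 0.68 (limma adjusted p = 0.0779, 0.135 and 0.0729).

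**Figure D3:**
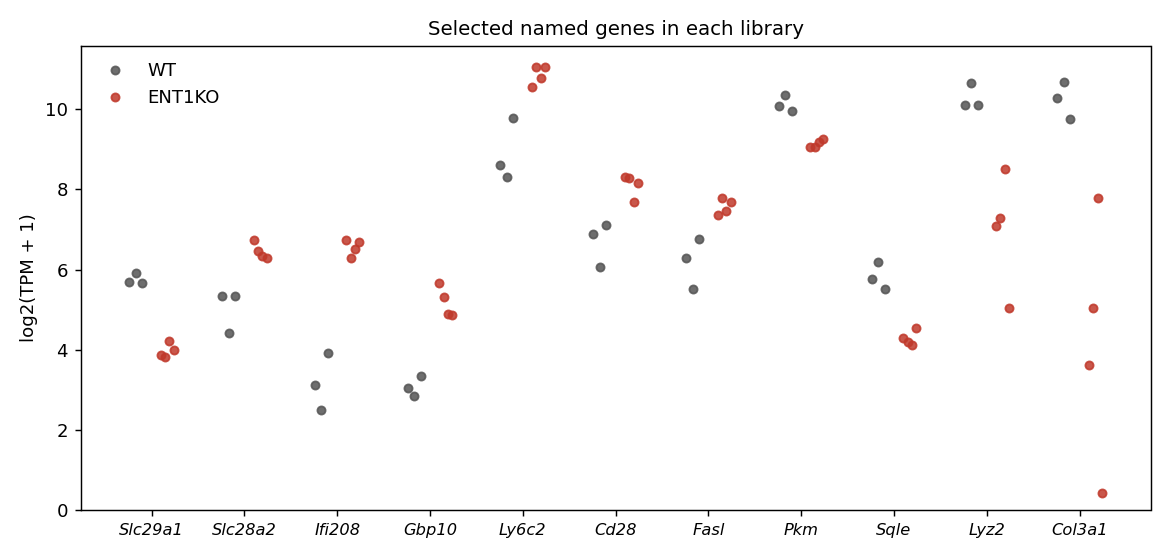
Log2(TPM + 1) of 11 named genes (horizontal axis) in each library, with WT in grey and ENT1KO in red. Slc29a1 averages 14.8 TPM in ENT1KO and 53.2 TPM in WT, Ifi208 93.9 and 8.85 TPM, and Col3a1 66.1 and 1251 TPM.

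T cell function genes were higher in TPM in ENT1KO, in the libraries in which the CD8 T cell identity list was 1.14 higher, and not relative to that list. In the naive, stem-like and memory list 12 of 16 genes rose and 1 fell (camera adjusted p = 0.00827; adjusted p = 0.601 with an estimated correlation). Tcf7 and Il7r rose by 1.39 and 1.54, and Foxp1 was at 62.4 ± 9.72 against 33.5 ± 4.86 TPM, while Id3 fell (6.91 ± 3.33 against 27.5 ± 7.85 TPM). Relative to the identity list the mean of this list was -0.30 (SE 0.20) and its median 0.03. Of 18 cytotoxic effector genes 12 rose and 1 fell (camera adjusted p = 0.0225; adjusted p = 0.671 with an estimated correlation), with a mean of -0.32 (SE 0.27) relative to the identity list. Fasl (191 ± 25.3 against 76.7 ± 31.2 TPM), Gzmb and Prf1 rose, the latter pair by 1.17 and 1.10, and Lamp1, a lysosomal protein of many cell types, fell (114 ± 11.2 against 289 ± 62.9 TPM). Of 14 inhibitory receptor and exhaustion genes 5 rose and none fell (camera adjusted p = 0.048; adjusted p = 0.671 with an estimated correlation; relative mean -0.53 (SE 0.21)), with Ctla4, Eomes (39.8 ± 12.3 against 16.1 ± 6.84 TPM) and Tigit among them. Pdcd1 and Tox did not pass, at log2 differences of 0.58 and 0.52. The tissue residency list had 7 rises and no fall among 12 genes (camera adjusted p = 0.0402; adjusted p = 0.601 with an estimated correlation; relative mean -0.50 (SE 0.20)), with Rgs2 at 759 ± 122 against 386 ± 80.6 TPM and Itga1 at 40.2 ± 11.5 against 18.3 ± 6.18 TPM. These counts were unchanged when adjusted over the list alone except for exhaustion, with 3 rises. Leaving out ENT1KO replicate 12 took the cytotoxic list to a camera adjusted p of 0.0592 and leaving out WT replicate 2 took tissue residency to 0.0788, and the exhaustion list passed only without ENT1KO replicate 15 or WT replicate 3 when 1 library was left out, with 0.122 without ENT1KO replicate 12. After quantile normalization the cytotoxic, exhaustion and tissue residency lists did not pass (camera adjusted p = 0.0824, 0.139 and 0.0846). Their medians were then 0.93, 0.57 and 0.79 against 1.10, 0.59 and 0.80 on TPM. On normalized counts the exhaustion list did not pass, at a median of 0.44 (camera adjusted p = 0.0505). Fry did not call the cytotoxic and exhaustion lists (fry adjusted p = 0.102 and 0.138).

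Lists of effector differentiation, activation and migration did not pass. The terminal effector list had 4 rises and 1 fall among 12 genes (camera adjusted p = 0.238), with Gzma at 248 ± 84.03 against 115 ± 41.97 TPM and Id2 at 393 ± 104 against 218 ± 48.7 TPM; without WT replicate 2 both lost their calls (limma adjusted p = 0.0773 and 0.0657), Gzma also without WT replicate 1 (0.0634). Of 18 activation and costimulation genes 9 rose and 2 fell (camera adjusted p = 0.0903; 10 higher and 2 lower when adjusted over the list alone), and the list passed without ENT1KO replicate 15 (0.0234) or WT replicate 3 (0.0337). Cd28 (279.6 ± 51.7 against 107 ± 36.3 TPM) and Icos rose, and Egr1, an immediate early gene, fell (71.5 ± 20.6 against 244 ± 104 TPM). Of 17 chemokine and receptor genes 7 rose and 3 fell (camera adjusted p = 0.401). Those that rose were receptors and ligands of T cells such as Cxcr3 and Ccl5, and the 3 that fell were the ligands Ccl9 (17 ± 10.5 against 93.8 ± 35.5 TPM), Cxcl9 and Cxcl10, which macrophages also make. The terminal effector and chemokine counts were the same over the list alone.

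Interferon response genes were higher in TPM in ENT1KO, and relative to the identity list neither interferon list passed. In the type I interferon list 18 of 30 genes rose and 2 fell (21 higher and 2 lower when adjusted over the list alone), with a median of 0.60 (camera adjusted p = 0.000944; adjusted p = 0.601 with an estimated correlation) and a mean of -0.70 (SE 0.39) relative to the identity list (exact permutation p = 0.0857). Ifit2 was at 49.8 ± 1.24 against 26.8 ± 0.384 TPM and Ddx58, which encodes the RNA sensor RIG-I, at 79.8 ± 6.17 against 41.2 ± 5.45 TPM; Mx1 rose by 1.43, and Oasl2 and Ifi44 fell. Of 22 interferon gamma response genes 16 rose and 3 fell, also over the list alone (camera adjusted p = 0.0089; adjusted p = 0.601 with an estimated correlation), with a mean of -0.81 (SE 0.35) relative to the identity list (exact permutation p = 0.0571). Gbp4 (154 ± 12.1 against 62.2 ± 13.8 TPM) and Gbp7 (87.2 ± 2.18 against 41.02 ± 7.87 TPM) rose with Gbp6, Gbp8 and Gbp9, whereas Cxcl9, Cxcl10 and Ciita fell together with the macrophage list.

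The fixed lists of nucleotide synthesis and salvage did not pass in camera, although single members changed and fry called 1 of them. In the de novo pyrimidine list 3 of 15 genes fell and none rose, also over the list alone (median -0.07, camera adjusted p = 0.25). The 3 were Uck2 (53.7 ± 7.04 against 93.5 ± 9.89 TPM), a uridine-cytidine kinase known for pyrimidine salvage although the fixed list holds it, Nme2 (166 ± 17.1 against 251 ± 32.6 TPM) and Ctps, CTP synthase (log2 -0.63); Nme2 had an adjusted p of 0.0542 in the authors' deposited table and did not pass on normalized counts, at -0.51 (limma adjusted p = 0.067). Cad, Dhodh and Umps, the enzymes that build UMP, did not pass, at 0.06, 0.16 and -0.28. On normalized counts the list passed (camera adjusted p = 0.0277), as it did after quantile normalization (0.0404). Of 14 pyrimidine salvage and catabolism genes 5 rose and 4 fell (7 higher and 4 lower when adjusted over the list alone; camera adjusted p = 0.966), with a median of 0.06 but a mean of -0.36. Uckl1 rose (50.6 ± 2.06 against 29.8 ± 2.11 TPM) and Cda, cytidine deaminase, fell (0.445 ± 0.699 against 10.5 ± 3.85 TPM), as did Upp1, uridine phosphorylase (-2.78). The de novo purine list had 3 rises and 2 falls among 12 genes (camera adjusted p = 0.781; median -0.14, mean 0.01), with Adss at 87.5 ± 3.77 against 57.97 ± 7.04 TPM and Impdh1 at 57.5 ± 5.401 against 36.9 ± 5.76 TPM. Of 15 purine salvage and adenosine metabolism genes 2 rose and 6 fell (camera adjusted p = 0.254). Fry, which does not compare a list with other genes, called this list lower (fry adjusted p = 0.0108). Aprt (82.9 ± 3.93 against 136 ± 16.3 TPM), Pnp (48.97 ± 5.09 against 84.6 ± 10.1 TPM) and Adk, adenosine kinase (-0.65), fell and Dpp4 rose (1.73). Counts of both purine lists were the same over the list alone. In these libraries the identity list was 1.14 higher and the macrophage list -3.07.

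Other nucleoside transporters and adenosine response genes also differed. Slc28a2, a concentrative nucleoside transporter, rose (87.8 ± 13.3 against 33.3 ± 11.2 TPM, limma adjusted p = 0.0028), and Slc29a2, the equilibrative paralogue ENT2, fell by 0.69 on the log2 scale. The transporter list with Slc29a1 in it had 1 rise and 2 falls among 4 genes (camera adjusted p = 0.254; 1 higher and 3 lower when adjusted over the list alone). Fry called it lower (fry adjusted p = 0.00355), with the targeted gene among its members. Relative to the identity list Slc28a2 was 0.24 higher and did not pass (limma adjusted p = 0.489). Of 13 adenosine receptor and cAMP response genes 8 rose and 1 fell, also over the list alone (camera adjusted p = 0.048; adjusted p = 0.671 with an estimated correlation; relative mean -0.63 (SE 0.20)). Adora2a, an adenosine receptor of T cells, rose by 1.01, Sik1, a cAMP-induced kinase, was at 149 ± 13.6 against 77.1 ± 15.5 TPM, and Adora2b fell (0.448 ± 0.128 against 2.29 ± 0.383 TPM). The call of this list was lost without any one of ENT1KO replicates 11, 12 and 14 or WT replicates 1 and 2, with camera adjusted p from 0.0533 to 0.107. It was also lost after quantile normalization (median 0.66 against 0.81 on TPM, camera adjusted p = 0.0968) and on normalized counts (median 0.65, camera adjusted p = 0.0515). Fry did not call the list (fry adjusted p = 0.0972).

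Glycolysis, hypoxia and sterol genes were lower in ENT1KO, in the libraries in which the fibroblast and tumour list was -4.79 and the macrophage list -3.07 on the same scale. Of 21 cholesterol synthesis genes 16 fell and none rose, also over the list alone, with a median of -0.69 (camera adjusted p = 2.18e-05; adjusted p = 0.601 with an estimated correlation). Sqle, squalene epoxidase, was at 18.6 ± 2.61 against 56.8 ± 14.2 TPM and Fdps at 56.3 ± 15.2 against 199 ± 57.8 TPM. Of 19 glycolysis genes 13 fell and 3 rose, also over the list alone (camera adjusted p = 0.0028; adjusted p = 0.601 with an estimated correlation). Pkm (563 ± 36.8 against 1131 ± 161 TPM) and Pgam1 (185 ± 22.5 against 428 ± 67.4 TPM) fell, and Slc2a3, Pfkp and Hk1 rose. In the hypoxia list 11 of 18 genes fell and 1 rose (2 higher and 12 lower when adjusted over the list alone; camera adjusted p = 0.000832; adjusted p = 0.601 with an estimated correlation), with Bnip3 at 26.7 ± 1.896 against 106 ± 26.97 TPM and Egln3 at 6.25 ± 2.09 against 56.1 ± 21.5 TPM. In the integrated stress response list 6 of 17 fell and 1 rose (0 higher and 6 lower when adjusted over the list alone; camera adjusted p = 0.0121; adjusted p = 0.601 with an estimated correlation). Asns, asparagine synthetase, was at 4.86 ± 0.873 against 26.1 ± 8.36 TPM and Cebpb at 24.9 ± 2.67 against 56.3 ± 12.6 TPM, while Atf4 and Ddit3 did not pass, at -0.17 and 0.04. Nuclear-encoded genes of oxidative phosphorylation had 1 rise and 4 falls among 32 (camera adjusted p = 0.343; 0 higher and 2 lower when adjusted over the list alone), with Sdhc at 95.1 ± 8.92 against 129 ± 2.76 TPM and Ndufb8 at 116 ± 5.84 against 152 ± 5.47 TPM. This list passed as lower after quantile normalization (median -0.18, camera adjusted p = 0.002) and on normalized counts (median -0.19, camera adjusted p = 0.021), against a median of -0.04 on TPM. Mitochondrially encoded transcripts were 4.73% ± 0.574 of TPM in ENT1KO and 10.95% ± 2.701 in WT. Of those 13 genes 11 fell, also over the list alone (camera adjusted p = 0.000258; adjusted p = 0.601 with an estimated correlation), and on normalized counts the list did not pass (camera adjusted p = 0.414). Its median there was still -0.84, against -1.03 on TPM.

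Part of the mitotic genes were lower and ribosomal protein genes higher in TPM in ENT1KO. In these libraries the fibroblast and tumour list was -4.79 and the macrophage list -3.07. In the G2/M list 10 of 31 genes fell and none rose (0 higher and 9 lower when adjusted over the list alone; camera adjusted p = 0.0028; adjusted p = 0.671 with an estimated correlation). Fry did not call this list (fry adjusted p = 0.167). Anln (8.66 ± 2.66 against 33.9 ± 10.9 TPM) and Ccnb1 (14.9 ± 3.48 against 36.6 ± 7.21 TPM) fell with Cdk1, Aurka and Plk1, whereas Mki67 and Top2a did not pass, at 0.48 and 0.15. Of 26 S phase genes 2 rose, Rpa2 (76.6 ± 7.797 against 43.6 ± 7.86 TPM) and Slbp (144 ± 15.3 against 103 ± 20.6 TPM), and 1 fell (1 higher and 0 lower when adjusted over the list alone; camera adjusted p = 0.864). Slbp did not pass in 5 of the 7 fits that left out 1 library, nor on normalized counts (0.32, limma adjusted p = 0.0507) or after quantile normalization (0.34, limma adjusted p = 0.0715). Of 36 cytosolic ribosomal protein genes 26 rose and none fell (26 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.000105; adjusted p = 0.671 with an estimated correlation), by a median of 0.38, and relative to the identity list they were lower, at a mean of -0.79 (SE 0.28). Rps24 was at 7127 ± 351 against 4176 ± 941 TPM and Rps20 at 517 ± 37.95 against 363 ± 17.8 TPM. The p53 and replication stress list had 5 rises and 3 falls among 20, also over the list alone (camera adjusted p = 0.955; median 0.14, mean -0.09), with Cdkn1a, the cell cycle inhibitor p21, at 17.3 ± 2.55 against 50.96 ± 10.7 TPM and Phlda3 at 1.36 ± 0.859 against 10.4 ± 2.22 TPM. The MYC target and ribosome biogenesis list had 2 rises and 3 falls among 26 (1 higher and 3 lower when adjusted over the list alone; camera adjusted p = 0.999), with Eif4e at 125 ± 8.98 against 180.4 ± 11.3 TPM and Nop16 at 28.6 ± 4.44 against 44.9 ± 3.37 TPM. Replication-dependent histone genes had 1 rise and 2 falls among 14 (0 higher and 2 lower when adjusted over the list alone; camera adjusted p = 0.215). In the dissociation and heat shock list 10 of 20 genes fell, such as Fos and Ier3, and 2 rose, also over the list alone (camera adjusted p = 0.0105; adjusted p = 0.601 with an estimated correlation).

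**Figure D4:**
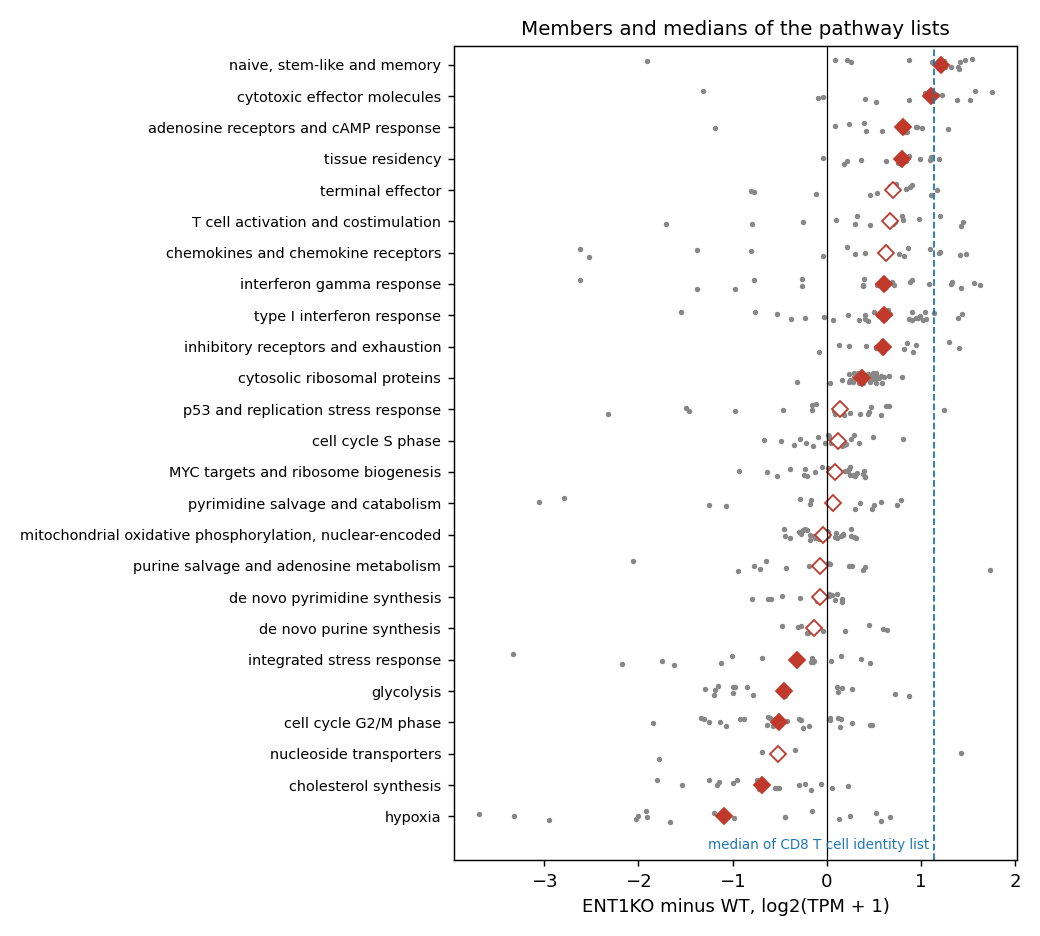
Log2(TPM + 1) differences, ENT1KO minus WT (horizontal axis), of the tested members of the 25 pathway lists (grey points) and their medians (diamonds, filled where camera's adjusted p was under 0.05). The dashed line marks the median of the CD8 T cell identity list, 1.14, and 13 of the 25 lists are filled.

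In all, 22 of the 39 tested lists passed with camera at the preset correlation of 0.01, 9 higher and 13 lower in ENT1KO, and none passed with an estimated correlation.

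Genes near Slc29a1 on chromosome 17 were compared with the rest, since a knockout allele can carry flanking sequence of another strain. Within 10 Mb of the gene, 74 of 130 tested genes passed, 33 higher and 41 lower, against 6907 of 13667 other genes (odds ratio 1.29, 95% interval 0.900 to 1.87, Fisher's exact two-sided p = 0.159). With 50.5% of the other genes called, this comparison could miss an effect of flanking sequence and does not exclude it.

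The authors' deposited table gave 7990 genes at its adjusted p of 0.05, 3113 higher and 4877 lower in ENT1KO. Among the 13798 genes tested here the authors' deposited table called 6808, of which 5802 were also called here, where independent lists would share 3445. Both sets of calls come from the same libraries, so their overlap is no independent support. The sign was the same for 5801 of those 5802, the exception being Rpl36a-ps2, a ribosomal protein pseudogene named here after its values were seen (0.28 here and -1.25 in the authors' deposited table). In the authors' deposited table the log2 fold change was 3.31 for Ifi208, 1.88 for Gbp10, 1.69 for Ly6c2, -4.43 for Col3a1 and -3.03 for Lyz2.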

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

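The tests of explanations in this part were chosen after the results were seen. Of 130 values examined in the 4 ENT1KO libraries, 8 had a library far from the other 3 by Dixon's test at its 95% critical value, where chance would give about 6.5.

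In ENT1KO replicate 14, Col3a1 was 221 TPM against 0.340 to 32.0 in the other ENT1KO libraries, and Col1a1 was 28.4 TPM against 0.0600 to 4.67. In the same library Lamp1 was 131 TPM against 106 to 110 and Nop16 was 35.3 TPM against 26.1 to 26.8. In ENT1KO replicate 12, Art2b was 4.72 TPM against 10.4 to 10.9. The summed cytotoxic effector list was 9240 TPM there against 6240 to 6730, and the summed NK cell list 1710 TPM against 1100 to 1140. S100a9 was 3.54 TPM in ENT1KO replicate 15 against 0.770 to 1.06.

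Tumour and myeloid marker genes were lower in the ENT1KO libraries, although the sort kept CD45-positive CD8-positive cells. RNA of tumour or stromal cells needs the genes of such cells to vary together between libraries of 1 genotype too, and the correlation between genes of the fibroblast and tumour list within the genotypes, as camera estimates it, was 0.89, with Col3a1 at 1251 TPM and Postn at 1295 TPM in WT. The same estimate was 0.93 for the CD8 T cell identity list, 0.7 for the G2/M list and 0.155 for the B cell list. A high value is therefore not particular to tumour or stromal genes. A lower share of T cells that raised every other cell type alike in WT would leave little gap between cell type lists. The median of the fibroblast and tumour list lay -4.997 from that of the B cell list on the log2 scale (exact two-sided Wilcoxon test across 19 and 7 genes, which are not independent, p = 6.08e-06). The B cell list was picked with the values known, and 2 of its 7 tested genes rose while 2 fell. It is thus a poor gauge of B cells, and that gap cannot decide. For the 6 cell type lists that passed as lower, the summed level in WT over ENT1KO was also unlike. It was 20.6 for fibroblast and tumour, 8.36 for neutrophil and mast cell, 7.84 for erythroid and platelet, 3.31 for dendritic, 2.2 for macrophage and 1.68 for endothelial genes. These values argue against an equal rise of every other cell type, although members that T cells also express could set the lists apart. The values are consistent with more tumour or stromal RNA in the WT libraries as a candidate explanation. A programme shared by these genes within the sorted cells would also give that correlation, and RNA of myeloid cells was not tested apart. Whether it came from the genotype, through the makeup of the tumours, or from the sort or its day stays open, since the labels give no batch.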

How the results depend on the processing

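The covariates and scaling tied to cell type lists, and camera's correlation, changed calls most; the fibroblast covariate, the identity list scaling and the test on normalized counts were chosen after the data were seen. Over all results and settings, 2147 comparisons were counted as the same, 277 as weaker, 30 as stronger and 63 as reversed. Weaker means a lost call or a clearly smaller count, and stronger a gained call or a clearly larger count. Reversed means a changed direction with a call before or after. A changed direction without any call was counted as the same. With the macrophage covariate, 4 genes were called (2 higher, 2 lower), Slc29a1 was -1.56 and 4 cell type lists passed. With the fibroblast and tumour covariate, limma called 0 genes (0 higher, 0 lower; 1241 at an unadjusted p under 0.05), Slc29a1 was -1.49 (limma adjusted p = 0.496, over its alternatives 1.85e-14 to 0.496) and 4 cell type lists passed. The summed levels of both lists are free of overlap between the genotypes, so these covariates can hardly be told apart from genotype, which widens the error of the genotype term. With the macrophage covariate the log2 values that reversed were Col3a1 1.79, Postn 1.93, Sparc 1.08, Bgn 0.71, Col1a2 0.12, Crabp1 1.94, Tm4sf1 1.33, Id2 -0.0846, Lyz2 0.47, H2-Eb1 0.27, H2-Aa 0.26, macrophage and monocyte markers 0.02898. With the fibroblast and tumour covariate they were Col3a1 2.19, Postn 2.23, Sparc 1.505, Mgp 0.31, Bgn 1.08, Col1a2 0.55, Serpinh1 0.23, Crabp1 2.24, Tm4sf1 1.63, Lyz2 0.45, H2-Eb1 0.25, H2-Aa 0.22, Pecam1 -0.0789. None of these reversed values passed the threshold with either covariate. On log2(normalized count + 1) Erdr1 -0.94 reversed; the cause was not tested. Relative to the CD8 T cell identity list, 22 genes were higher, 9255 lower and 23 lists passed, since by construction each value is lowered by the identity list's rise, and the reversed values given here were Uckl1 -0.44, Adss -0.59, Impdh1 -0.55, Sik1 -0.23, Foxp1 -0.31, Gzma -0.0809, Id2 -0.34, Rgs2 -0.197, Itga1 -0.0748, Rpa2 -0.37, Slbp -0.69, Ifit2 -0.31, Ddx58 -0.24, Gbp7 -0.0947, Rps24 -0.39, Rps20 -0.67, Trac -0.0124, Ighm -0.34, Pecam1 -0.55, Sfn -0.13, pyrimidine salvage and catabolism -1.12, adenosine receptors and cAMP response -0.37, cytotoxic effector molecules -0.0828, inhibitory receptors and exhaustion -0.59, naive, stem-like and memory 0.03003, terminal effector -0.48, tissue residency -0.38, T cell activation and costimulation -0.51, chemokines and chemokine receptors -0.56, cell cycle S phase -1.07, p53 and replication stress response -1.05, type I interferon response -0.58, interferon gamma response -0.58, MYC targets and ribosome biogenesis -1.098, cytosolic ribosomal proteins -0.81, CD4 and regulatory T cell markers -0.69. Of these, the median of the naive, stem-like and memory list kept its sign, and its mean turned, to -0.30 (SE 0.20). The median of all tested genes was -1.04 on that scale, so a list below 0 there need not be low against other genes. With an estimated correlation 0 pathway or quality lists and 0 cell type lists passed in camera, where the preset correlation gave 15 and 7 and fry gave 13 and 8. The overlap with the authors' deposited table was 2933 genes at an absolute log2 fold change over 1, since fewer genes enter.

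Leaving out 1 library gave 4840 to 6853 called genes, 2315 to 3748 higher and 2525 to 3145 lower, with the lowest counts without WT replicate 2, where 4816 of the 6982 calls were shared with the same sign. Slc29a1 stayed between -1.86 and -1.71, pathway and quality lists between 12 and 16, cell type lists at 7. The exact p of the sample structure was 0.0667 to 0.1, the smallest that the 6 samples left allow. No result reversed when 1 library was left out, nor under quantile normalization, other filters, array weights, pseudocounts or protein-coding genes alone. The odds ratio near Slc29a1 was 1.18 within 2 Mb and 1.19 within 20 Mb. Of the called genes, 8 were higher and 21 lower within 2 Mb, and 121 higher and 110 lower within 20 Mb. The balance of directions near the gene was not tested. No paired analysis was possible because the genotypes share no replicate numbers. Not run were the count-based alternatives (other size factors, voom and the Wald test on counts) and the surrogate variable, which need a count test, and sex as a covariate, since the sexes were not mixed. Depth of 18624318 to 19660792 reads does not separate the genotypes.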

Other observations

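The tests of explanations in this part were chosen after the results were seen. Of 22 genes higher in ENT1KO beyond the CD8 T cell identity list in limma, 10 were protein-coding, 4 lay in the p200 cluster on chromosome 1 and 2 were Gvin pseudogenes of an interferon-inducible GTPase family. The T cell receptor segments Trav12-2 (139.7 ± 64.2 against 22.4 ± 15.3 TPM) and Trbv1 (97.9 ± 46.01 against 22.5 ± 12.6 TPM) were among them, with a wide spread between ENT1KO libraries. Gm18736, an unnamed model 19.8 Mb from Slc29a1 on chromosome 17, was at 10.04 ± 0.736 against 0.217 ± 0.231 TPM, and H4c17 was listed at 0 in each WT library and at 4.24 ± 1.98 TPM in ENT1KO. These genes are named after their values were seen, and limma adjusted p relative to the identity list are too small. Of 12 tested genes of the p200 cluster, 8 rose and 4 fell in TPM, the latter being Ifi204, Ifi205, Ifi207 and Ifi211. Of 113 tested small nucleolar RNA genes 22 rose and 5 fell in TPM, whereas relative to the identity list 2 were higher and 26 lower. Xist was at 181 ± 15.9 TPM in ENT1KO and 68.3 ± 12.8 TPM in WT, 0.22 higher relative to the identity list, and Ddx3y and Eif2s3y were listed at 0 in each library.

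Other splits of the samples were compared with the real one. For genes changed between the genotypes, 1 of the 35 splits, the real one with 6982 genes, gave as many, and the highest other gave 1452. A chance split is thus excluded at 0.05 for the count as a whole. The count follows the separation already seen in the first principal component and is no separate support for single genes. For gene lists, 5 of the 35 splits gave at least 22 lists and the highest other gave 25, so chance cannot be excluded for the number of lists. For genes higher beyond the identity list, 2 of the 35 splits gave at least 22 genes, so this count does not exclude chance. The highest other split gave 2359, with ENT1KO replicate 14 and the 3 WT libraries on one side, which points to the structure of the samples seen in the first principal component. Those 2359 genes were higher on the side of the WT libraries. The count thus sets opposite directions side by side and cannot decide about chance.

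T cell function genes were higher in the ENT1KO libraries in TPM. Over the 88 tested genes of 6 lists, 48 rose and 5 fell, with a mean log2 difference of 0.677. A lower share of T cell RNA in the WT libraries as the cause allows no excess over the identity list, and the mean after subtraction was -0.505 (SE 0.184, exact permutation p = 0.0286), with 0 of the 88 genes higher in limma and 25 lower. The rises thus do not need higher expression per T cell. A lower share alone would also give no deficit. The test looked only for an excess, so it cannot account for the 25 lower genes. That count is itself too high, since limma adjusted p on this scale are too small. Of the 6 lists, terminal effector, activation and tissue residency had means of -0.72, -0.71 and -0.50 relative to the identity list (exact permutation p = 0.0286 for each). The cytotoxic, exhaustion and naive lists had means of -0.32, -0.53 and -0.30 (exact permutation p = 0.371, 0.0571 and 0.229). On that scale the median of all tested genes was -1.04, so a mean below 0 does not make a list low against other genes. Some members, such as Lamp1 and Egr1, are expressed by other cells too, which may lower the mean, but this was not tested. A change within the T cells stays open.

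The p200 family genes Ifi208, Ifi213 and Ifi214 were among the largest rises. A lower share of T cell RNA in the WT libraries cannot be told apart: 4 of the 12 tested genes of the cluster were higher than the identity list in limma, these 3 among them, which had been picked for their rise, whereas Ifi206, Ifi203, Ifi209 and Mndal did not pass, at 0.46, 0.17, 0.26 and 0.17. A general type I interferon response cannot be told apart either: its list had a mean of -0.697 after the same subtraction, but macrophages and tumour cells in the WT libraries may also express these genes. A genetic difference at the p200 cluster on chromosome 1 also stays open, since 3 of the 3 genes were free of overlap between genotypes after the subtraction, which their selection favours and regulation would also give, and the tables hold no sequence. No cluster gene was at 0 in every library of 1 genotype, but Gm18752, an unnamed model and the fourth gene above the identity list, was close to that in WT, at 0.19, 0 and 0.12 TPM against 3.27 to 5.3 TPM in ENT1KO (1.10 relative to the list, limma adjusted p = 0.032). A response to ENT1 loss itself was not tested apart from these, and reads shared within the family stay open.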
